A study of Pseudomonas aeruginosa with 8 samples.

How the data were processed

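RNA from Pseudomonas aeruginosa cultures was measured on single-colour expression arrays (the table held AFFX control probe sets), with biotin-labelled cRNA made from about 36 µg of total RNA per sample. The 8 arrays formed 4 groups of 2 biological replicates. Cu-adapted cultures grew for about 6 h with 10 mM copper to an OD600 of 0.2, and their controls grew to the same density untreated. Cu-shocked cultures received 10 mM copper for 45 min, and their controls received hydrochloric acid for 45 min to reach a similar pH. All cultures grew at 37 °C in LB buffered with 100 mM MOPS, and RNA was stabilised in RNAlater and purified with RNeasy columns, per the labels' protocols.

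The deposited values were probe set signal intensities on a linear scale, computed by the authors with MAS5, per the submitters' processing notes, which gave neither a version nor settings. The 2% trimmed mean of the deposited intensity over all 5896 probe sets lay between 2503 and 2505 on every array, so the authors had scaled the arrays to a common level. Array medians lay between 887 and 1058. The table held 0 columns of other samples. Scanner files and detection calls were not used here, and no genome build was named in the sources used here, so no coordinates are given. For arrays, the number of arrays limits the precision, and low signals have no measured background beside them here.

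From these values, each array was scaled again to a common 2% trimmed mean, a small adjustment because they were already scaled, and log2(value + 16) was taken. A fold change on the log2(value + 16) scale understates the change of genes with low signal. The 14 AFFX control probe sets were left out, which left 5882 probe sets for testing: 5545 for genes of strain PAO1, 199 for intergenic regions and 138 other P. aeruginosa probe sets. The platform annotation gave 1 gene symbol for 5500 probe sets, several for 0 and none for 382. All 5500 matched the RefSeq gene table (assembly ASM676v1) by gene ID, with equal locus tags, and the table was used for names and gene order. A gene without a name in these tables is given by its locus tag.

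Linear models with a mean per group were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that followed an intensity trend (4 residual degrees of freedom, prior degrees of freedom 3.9). The spread was shared over the 4 groups because each held 2 arrays. The 4 comparisons were Cu shock against its acid-treated control, Cu-adapted growth against its untreated control, the difference between these responses, and the acid-treated against the untreated control. In the last comparison the acid and the separate experiments cannot be told apart. A probe set was called changed at a Benjamini-Hochberg adjusted p below 0.05, and an error beside a log2 difference is its standard error from this fit. Errors beside signals are standard deviations over 2 arrays. Genes changed the same way in both copper comparisons were counted, beside the overlap of independent lists and a 2-sided Fisher exact test for each of the 4 pairs of directions. These comparisons have separate control arrays but share the estimate of spread.

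The 24 gene lists held 519 loci, of which 512 were measured: copper homeostasis, Czc and Cad metal efflux, pyoverdine, pyochelin, heme and ferrous or ferric iron uptake, iron-sulfur cluster assembly, zinc uptake, oxidative stress defence, heat shock and protein quality control, ribosomal proteins, ATP synthase, NADH dehydrogenase I, terminal oxidases, denitrification, type III secretion, outer membrane porins, flagella, RND multidrug efflux, quorum sensing and secreted virulence factors, phenazine synthesis, alginate synthesis, Psl and Pel exopolysaccharides, lipid A with the PhoPQ-PmrAB regulon, and the SOS response with R/F pyocins. Lists were tested with the limma camera test at a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, whereas fry tests whether a list's genes move one way on balance and does not compare them with other genes.

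The genes named for each copper comparison were the 12 largest rises and the 12 largest falls that passed the test, had both treated arrays on the same side of both control arrays, and reached a mean signal of at least 1100, the median of all probe sets, in the higher group. For the difference and for the controls, 5 in each direction were taken, for the difference without the rule on single arrays. Up to 4 passing members with the largest change were named per list, as were all copper homeostasis genes and oprC. The grouping, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except where a later choice is stated.

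The fit was tested on simulated data for 5882 genes, of which 200 were changed, in 5 simulations. For Cu shock it recovered 7.2%, 63.3% and 94.8% of genes changed by 1, 2 and 4 log2 units, with 4.8% of calls false. For Cu-adapted growth it recovered 9%, 62.4% and 92.7%, with 5% of calls false. The simulated genes were independent and had the same spread in all 4 groups. In the data the acid-treated arrays lay further apart than the other pairs, so these shares need not hold for the real comparisons. Alternatives were other scalings (quantile normalization, the values as deposited, median centring, trimmed mean centring), pseudocounts of 1 and 64, removal of the dimmest 25% of probe sets, no intensity trend, a robust variance prior, a 2-fold minimum, PAO1 probe sets alone, the replicate number as a block, separate fits to the 4 arrays of each comparison, and the omission of each array in turn. An array pair reduced to a single array by an omission was assumed to vary like the other groups. Cu shock against the untreated controls and against all 4 controls was added after the data were seen.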

Results

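Transcript levels of Pseudomonas aeruginosa, an opportunistic pathogen, were measured under copper stress on 8 arrays, 2 for each of 4 groups. A 45 min copper shock was set beside an acid-treated control, and growth for about 6 h with copper was set beside an untreated control. Both copper treatments used 10 mM. The array medians of the scaled signal lay between 887 and 1058. Across probe sets, which are not independent, replicate arrays correlated at 0.969 for the untreated controls, 0.973 for Cu-adapted growth, 0.965 for Cu shock and 0.897 for the acid-treated controls. The 2 acid-treated arrays differed by 2-fold or more for 1505 probe sets (25.6%), against 5.6% to 7.1% in the other groups, and their log2 differences had an SD of 1 against 0.51 to 0.56. This pair enters the spread of every comparison, so many counts below are also given without single arrays that moved them. The Cu shock arrays stood apart from the other groups, with correlations of 0.774 to 0.822. Of the acid-treated arrays, replicate 1 stood further from the untreated controls (0.886 with each) than replicate 2 (0.946 and 0.945).

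The first comparison asked which transcripts respond within 45 min of copper, beyond the response to acid. Copper homeostasis genes made up 8 of the 12 largest rises, and peroxide defence genes such as ohr rose by less. PA2807 rose at least 480-fold, the value after 16 was added to each signal, from a signal of 26.8 ± 5.15 (SD, n = 2) in the acid-treated control to 20477 ± 507 (n = 2). PA3920, a copper-exporting P-type ATPase, rose 144-fold on the same scale, from 496 ± 3.34 to 74083 ± 4726 (n = 2), and ohr, an organic hydroperoxide resistance gene, reached 83990 ± 9874 from 1665 ± 69.2 (n = 2). Among transcripts that fell were those of 15 of 18 genes in the lipid A and PhoPQ-PmrAB list, 12 of 13 NADH dehydrogenase I genes and the arginine-ornithine antiporter arcD.

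In the limma fit, 1781 of 5882 probe sets (30.3%) changed in Cu shock, 863 higher and 918 lower, against 2451 at an unadjusted p below 0.05. At least 2-fold changes numbered 745 higher and 749 lower, and at least 10-fold changes 87 higher and 15 lower. The count was 1058 without shock replicate 1 and 879 without shock replicate 2. Fitted to its own 4 arrays, the comparison gave 781. Set against the untreated controls instead, an alternative chosen after the data were seen, Cu shock changed 2060 probe sets, of which 673 were also higher and 676 also lower against the acid-treated control.

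The 12 largest rises in Cu shock ranged from 6.08 to 8.91 log2 units. They included PA2807 (8.91 ± 0.25, SE, adjusted p = 2.2e-06), PA3523 (8.45 ± 0.37, adjusted p = 1.2e-05), PA3237 (8.34 ± 0.72, adjusted p = 0.00027), PA3517 (7.57 ± 0.31), PA4471 (7.5 ± 0.65) and PA3518 (7.21 ± 0.48). PA3920, PA3521, PA3519, PA1541, PA3287 and PA3516 completed the set. PA3237 rose from 65.1 ± 55.2 to 23200 ± 3539 (n = 2) and PA3287 from 539 ± 170 to 38410 ± 935 (n = 2).

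The 12 largest falls in Cu shock lay between -4.29 and -3.38 log2 units. The transcripts of PA2114 (-4.29 ± 0.54, adjusted p = 0.0011), the porin gene opdO (-3.99 ± 0.5) and PA2116 (-3.89 ± 0.45) fell most. Their acid-treated controls were far apart, at 26483 and 7077 for PA2114, 25213 and 7206 for opdO, and 7042 and 2496 for PA2116. The transcript of arcD fell from 47905 ± 18870 to 3292 ± 400 (n = 2; -3.8 ± 0.34, adjusted p = 0.00029). The others were PA2119 (-3.71 ± 0.37), PA4328 (-3.7 ± 0.25), PA3913 (-3.58 ± 0.48), PA4348 (-3.38 ± 0.34), rsaL, a repressor gene of quorum sensing (-3.69 ± 0.31), and hemN, an oxygen-independent heme synthesis gene (-3.54 ± 0.39). PA0747 (-3.82 ± 0.85) and PA0746 (-3.55 ± 0.95) passed with all arrays. Without shock replicate 1 their adjusted p was 0.075 and 0.12, and without shock replicate 2 it was 0.07 and 0.11.

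**Figure D1:**
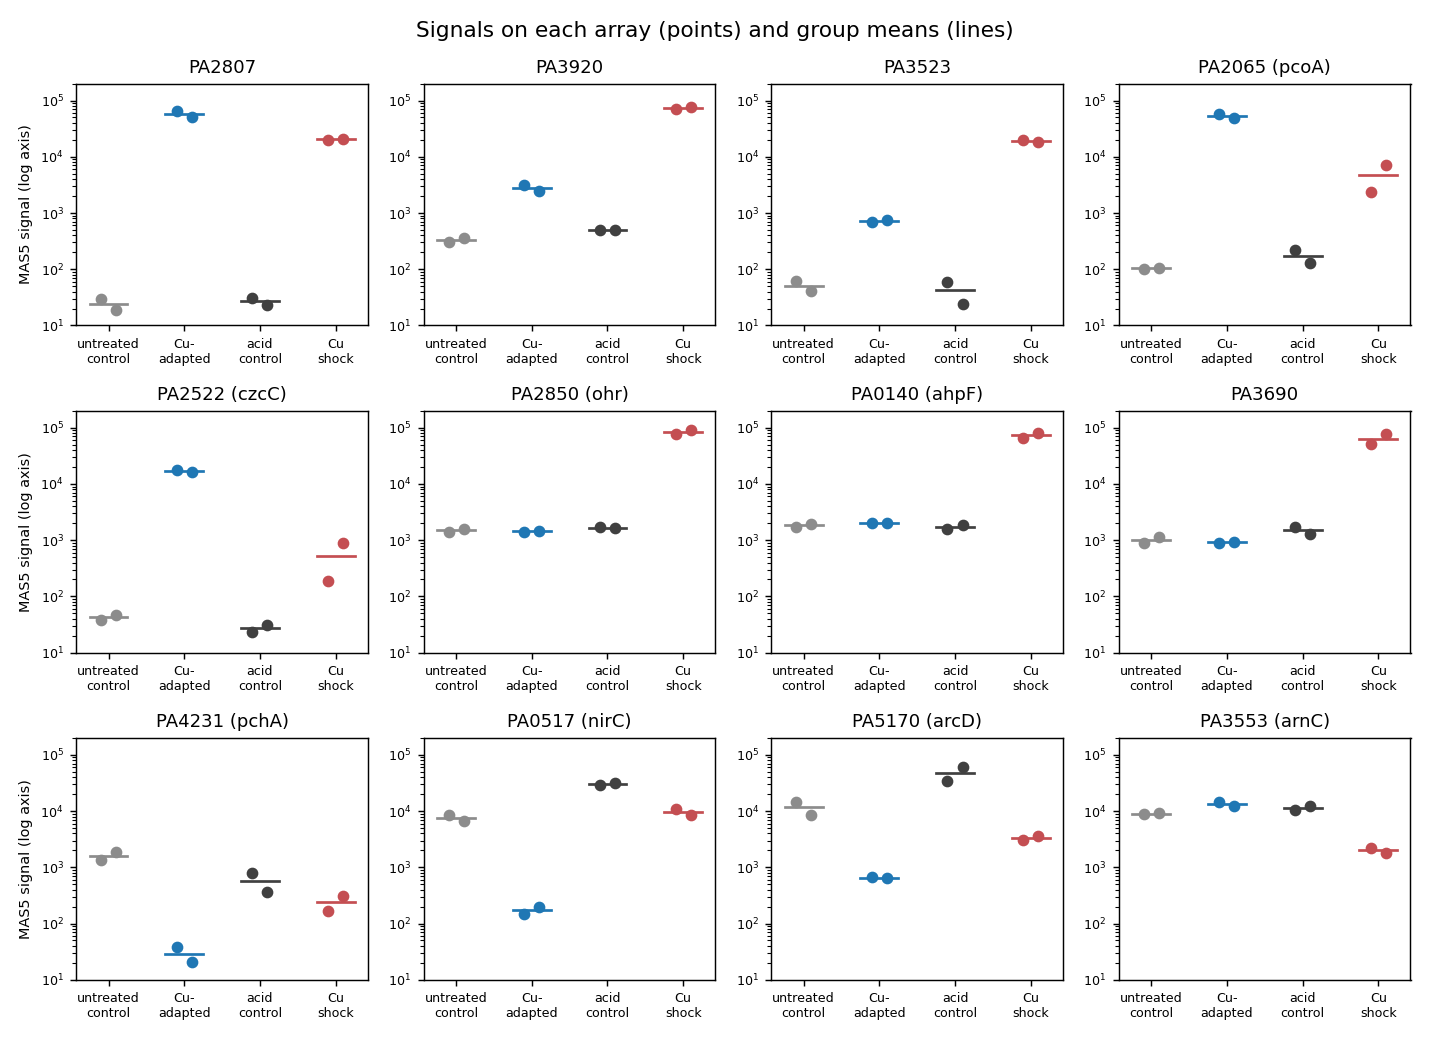
Scaled MAS5 signal (log axis) of 12 genes on each of the 8 arrays, by group, with group means as lines. PA2807 reached 20477 in Cu shock and 58061 in Cu-adapted growth against 26.8 and 24.4 in the controls.

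Of the 17 copper homeostasis genes, 16 rose and cueR, the copper-sensing regulator gene, fell in Cu shock (16 and 1 adjusted over the list alone). The list's median was 5.9 log2 units (camera adjusted p = 5.1e-13, adjusted p = 0.12 with an estimated correlation). PA3521, PA3522 and PA3523, which encode a tripartite efflux system, rose by 6.89 ± 0.43, 5.9 ± 0.34 and 8.45 ± 0.37 (SE). PA3515, PA3516, PA3517, PA3518 and PA3519 rose by 5.53, 6.08, 7.57, 7.21 and 6.89, and PA3520 by 2.21 ± 0.31. The multicopper oxidase gene pcoA rose by 4.48 ± 0.48, pcoB by 3.03 ± 0.39 and ptrA by 5.69 ± 0.34. The regulator genes copR and copS rose by 2.29 ± 0.38 and 1.16 ± 0.25, the latter not passing without shock replicate 1 (adjusted p = 0.068). The transcript of cueR fell by 1.52, and that of oprC, which encodes a copper-binding porin, fell by 2.72 (adjusted p = 0.0057). In this and the following lists, members named because they alone moved against the rest were chosen after the values were seen.

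Of 8 Czc and Cad metal efflux genes, 6 rose and 0 fell (6 adjusted over the list alone), with camera adjusted p = 0.0015 and adjusted p = 0.28 with an estimated correlation. PA3690, a P-type metal ATPase gene, rose by 5.4 ± 0.27 (SE) and the efflux gene czcC by 3.32 ± 0.61, while 3 of the 8 rose without shock replicate 2. Among 19 zinc uptake genes, 8 rose and 0 fell (8 adjusted over the list alone), with camera adjusted p = 0.0015 and adjusted p = 0.26 with an estimated correlation. They included PA5498 (2.07 ± 0.23), PA4834 (2.02 ± 0.34) and np20 (1.81 ± 0.24). Without shock replicate 1 the number was 3, and without shock replicate 2 it was 4.

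Of the 20 heme and ferrous or ferric iron uptake genes, 9 rose and hitB fell (9 and 1 adjusted over the list alone). Camera gave adjusted p = 0.0023 and adjusted p = 0.26 with an estimated correlation. The energy-transducing gene tonB1 rose by 4.57 ± 0.25, PA4709 by 4.29 ± 0.31 and phuT by 2.9 ± 0.26 (SE), and without shock replicate 2 the list had 5 rises and 2 falls. In the iron-sulfur cluster assembly list, 7 of 8 rose and 0 fell (8 adjusted over the list alone), with camera adjusted p = 1.6e-05 and adjusted p = 0.42 with an estimated correlation. The regulator gene iscR rose by 3.14 ± 0.32, hscB by 2.9 ± 0.29 and iscU by 2.59 ± 0.29. Relative to the untreated controls, this list's median was 1.57 and 1.78 on the Cu shock arrays and -1.29 and -0.3 on the acid-treated arrays.

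Of 19 pyoverdine genes, 8 rose and fpvA fell in Cu shock (9 and 1 adjusted over the list alone), with camera adjusted p = 0.0049 and adjusted p = 0.54 with an estimated correlation. Relative to the untreated controls, the list's median was 0.17 and 0.25 on the Cu shock arrays and -0.88 and -0.81 on the acid-treated arrays. The Cu shock arrays thus lay nearer the untreated level than the acid-treated arrays did. The untreated controls came from a separate experiment, so these values cannot tell an effect of acid from one of the experiment. The sigma factor gene pvdS rose by 4.1 ± 0.36 (SE). PA2393 rose by 2.68 ± 0.47 against an acid-treated control of 18.3 ± 12.7, below the untreated 231 ± 66 (n = 2), and against the untreated controls its difference was -0.19 (adjusted p = 0.79). Without shock replicate 1 the list had 4 rises, and without shock replicate 2 it had 2, with no fall of fpvA in either case. Of 14 pyochelin genes, the regulator gene pchR rose by 1.77 ± 0.31 and pchB and pchC fell (1 and 0 adjusted over the list alone). The pyochelin list had camera adjusted p = 0.5 and adjusted p = 0.82 with an estimated correlation. Its falls numbered 0 without shock replicate 1, shock replicate 2, shock control replicate 1 or either adapted array, 1 without either untreated control, and 5 without shock control replicate 2.

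Of 19 oxidative stress defence genes, 12 rose and 2 fell in Cu shock (12 and 2 adjusted over the list alone), with a median of 1.32, camera adjusted p = 1.5e-05 and adjusted p = 0.12 with an estimated correlation. The gene ohr rose by 5.64 ± 0.19 (SE), the alkyl hydroperoxide reductase gene ahpF by 5.42 ± 0.21, PA0848 by 5.31 ± 0.33 and the thioredoxin reductase gene trxB2 by 4.62 ± 0.22. The falls were those of sodB (-0.99 ± 0.27) and oxyR (-1.43 ± 0.25), named after their values were seen, and 1 of these did not pass without either shock or either adapted array. Of 40 SOS response and R/F pyocin genes, 16 rose and 0 fell (21 adjusted over the list alone), with camera adjusted p = 6.9e-08 and adjusted p = 0.45 with an estimated correlation. The repressor gene lexA rose by 2.3 ± 0.26, the recombinase gene recA by 2.2 ± 0.2 and PA3616 by 2.19 ± 0.26. Without shock replicate 1 the number of rises was 4, and without shock replicate 2 it was 3.

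Of 16 heat shock and protein quality control genes, 3 rose and 0 fell (2 adjusted over the list alone), with camera adjusted p = 0.21 and adjusted p = 0.75 with an estimated correlation. The small heat shock gene ibpA rose by 2.41 ± 0.34 (SE), rpoH by 0.97 ± 0.26 and lon by 0.68 ± 0.21. The calls of rpoH and lon were each lost without either shock array or any of the 4 adapted-experiment arrays (adjusted p = 0.05 to 0.15 and 0.06 to 0.16). The list had 1 rise without either shock or either adapted array, 5 rises and 2 falls without shock control replicate 1, and 1 fall without shock control replicate 2.

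Of 13 NADH dehydrogenase I genes, 12 fell and 0 rose in Cu shock (12 adjusted over the list alone), with camera adjusted p = 4.1e-06 and adjusted p = 0.45 with an estimated correlation. The transcripts of nuoL, nuoK and nuoM fell by 1.97, 1.89 and 1.6, and 4 of the list fell without shock replicate 2. Of 17 terminal oxidase genes, cioA and cioB of the cyanide-insensitive oxidase rose, and ccoN2, ccoO2 and ccoP2 fell (2 and 3 adjusted over the list alone). That list had camera adjusted p = 0.52 and adjusted p = 0.72 with an estimated correlation. The call of cioA was lost without shock replicate 2 (adjusted p = 0.065) and that of cioB without shock replicate 1 or 2 (adjusted p = 0.09 to 0.12). The transcript of ccoN2 fell from 35609 ± 7140 to 3821 ± 335 (n = 2). Rises and falls numbered 1 and 2 without shock replicate 1, 0 and 2 without shock replicate 2, 4 and 7 without shock control replicate 1, and 6 and 5 without shock control replicate 2.

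None of the 53 ribosomal protein genes passed in Cu shock (0 adjusted over the list alone; median -0.03, mean 0.09, camera adjusted p = 0.8, adjusted p = 0.97 with an estimated correlation). This rested on the acid-treated pair. Without shock control replicate 1, 27 fell, and without shock control replicate 2, 28 rose. Relative to the untreated controls, the list's median was -1.14 on shock control replicate 1, 0.18 on replicate 2, and -0.42 and -0.44 on the Cu shock arrays. None of the 9 ATP synthase genes passed (0 adjusted over the list alone; median -0.36, camera adjusted p = 0.5, adjusted p = 0.82 with an estimated correlation), while 7 fell without shock control replicate 1 and 1 rose without shock control replicate 2.

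Of 27 denitrification genes, narG and narJ rose and 5 fell in Cu shock (2 and 5 adjusted over the list alone), with camera adjusted p = 0.12 and adjusted p = 0.74 with an estimated correlation. The transcript of nirC fell by 1.67 from 30856 ± 1863 in the acid-treated control, which lay above the untreated control of 7483 ± 1327 (n = 2). Against the untreated controls nirC differed by 0.38 (adjusted p = 0.27) and PA0513, which fell by 1.65 against acid, by 0.26 (adjusted p = 0.6). The call of PA0513 was lost without shock replicate 2 (adjusted p = 0.078), that of narG without either shock array (adjusted p = 0.069 to 0.13) and that of narJ also without either adapted array or shock control replicate 2 (adjusted p = 0.051 to 0.15). Rises and falls numbered 1 and 8 without either adapted array, 0 and 5 without shock replicate 1, 0 and 2 without shock replicate 2, 4 and 5 without shock control replicate 1, and 1 and 7 without shock control replicate 2.

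Of 18 genes in the lipid A and PhoPQ-PmrAB list, 15 fell and 0 rose in Cu shock (16 adjusted over the list alone), with a median of -1.8, camera adjusted p = 1.3e-08 and adjusted p = 0.35 with an estimated correlation. The transcript of arnC, for addition of aminoarabinose to lipid A, fell from 11376 ± 1123 to 2022 ± 302 (n = 2; -2.49 ± 0.21, SE, adjusted p = 0.00027), and those of phoP, PA4775 and arnD fell by 2.37, 2.31 and 2.23. A single member rose without shock control replicate 2. Of 41 flagellar genes, 14 fell and 0 rose (14 adjusted over the list alone), with camera adjusted p = 0.00014 and adjusted p = 0.42 with an estimated correlation. The hook-filament junction genes flgL and flgK fell by 1.99 and 1.98, and 7 and 9 of the list fell without shock replicates 1 and 2, and 1 rose without shock control replicate 2. Of 18 Psl and Pel exopolysaccharide genes, pslA rose and 5 fell (1 and 5 adjusted over the list alone), with camera adjusted p = 0.23 and adjusted p = 0.67 with an estimated correlation. The falls included pslF (-1.37 ± 0.27), and numbered 1 without shock replicate 2, where pslA did not pass either, and 8 without shock control replicate 1.

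Of 26 outer membrane porin genes, opdC rose and opdO, oprC, oprD and oprG fell in Cu shock (1 and 4 adjusted over the list alone), with camera adjusted p = 0.5 and adjusted p = 0.67 with an estimated correlation. The transcript of oprD, a porin for basic amino acids, fell by 2.2. Rises and falls numbered 0 and 4 without either shock array, 4 and 5 without shock control replicate 1, and 5 and 9 without shock control replicate 2. Of 28 RND multidrug efflux genes, 10 rose and PA2525 fell (11 and 1 adjusted over the list alone), with camera adjusted p = 0.012 and adjusted p = 0.26 with an estimated correlation. PA2528 rose by 2.59 ± 0.25 (SE), mexG by 1.93 ± 0.29 and PA1435 by 1.75 ± 0.32. The rises numbered 5 without shock replicate 1, 4 without shock replicate 2 and 6 without either adapted array, and 3 fell without shock control replicate 2. The fall of PA2525 was lost without shock replicate 1 or either adapted array.

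Of 21 quorum sensing and secreted virulence genes, the lectin gene lecA rose and 8 fell in Cu shock (1 and 11 adjusted over the list alone), with camera adjusted p = 0.0071 and adjusted p = 0.47 with an estimated correlation. The signal synthase gene rhlI fell by 2.37, and the hydrogen cyanide synthesis genes hcnB and hcnA fell by 2.32 and 2.01. Against the untreated controls hcnB and hcnA did not pass (adjusted p = 0.13 and 0.15). Relative to those controls, the list's median was 0.25 and -0.22 on the Cu shock arrays and 0.94 and 0.49 on the acid-treated arrays. The Cu shock arrays thus lay nearer the untreated level than the acid-treated arrays did. Acid and the separate experiments cannot be told apart in these values, so they do not assign the list's fall to either. The falls numbered 4 without shock replicate 2, and the rise of lecA was lost without either shock array, either adapted array or either untreated control. Of 40 type III secretion genes, pscU rose and exsC and PA3842 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.75 and adjusted p = 0.82 with an estimated correlation. Of 10 phenazine genes, phzD2 rose (0 adjusted over the list alone; camera adjusted p = 0.79, adjusted p = 0.82 with an estimated correlation). The calls of pscU and PA3842 were lost without each of 7 single arrays, that of phzD2 without 5 and that of exsC without 3, shock replicate 2 among them in each case (adjusted p = 0.051 to 0.23), while 2 type III genes rose without shock control replicate 1. None of 12 alginate genes passed (0 adjusted over the list alone; camera adjusted p = 0.5, adjusted p = 0.67 with an estimated correlation).

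**Figure D2:**
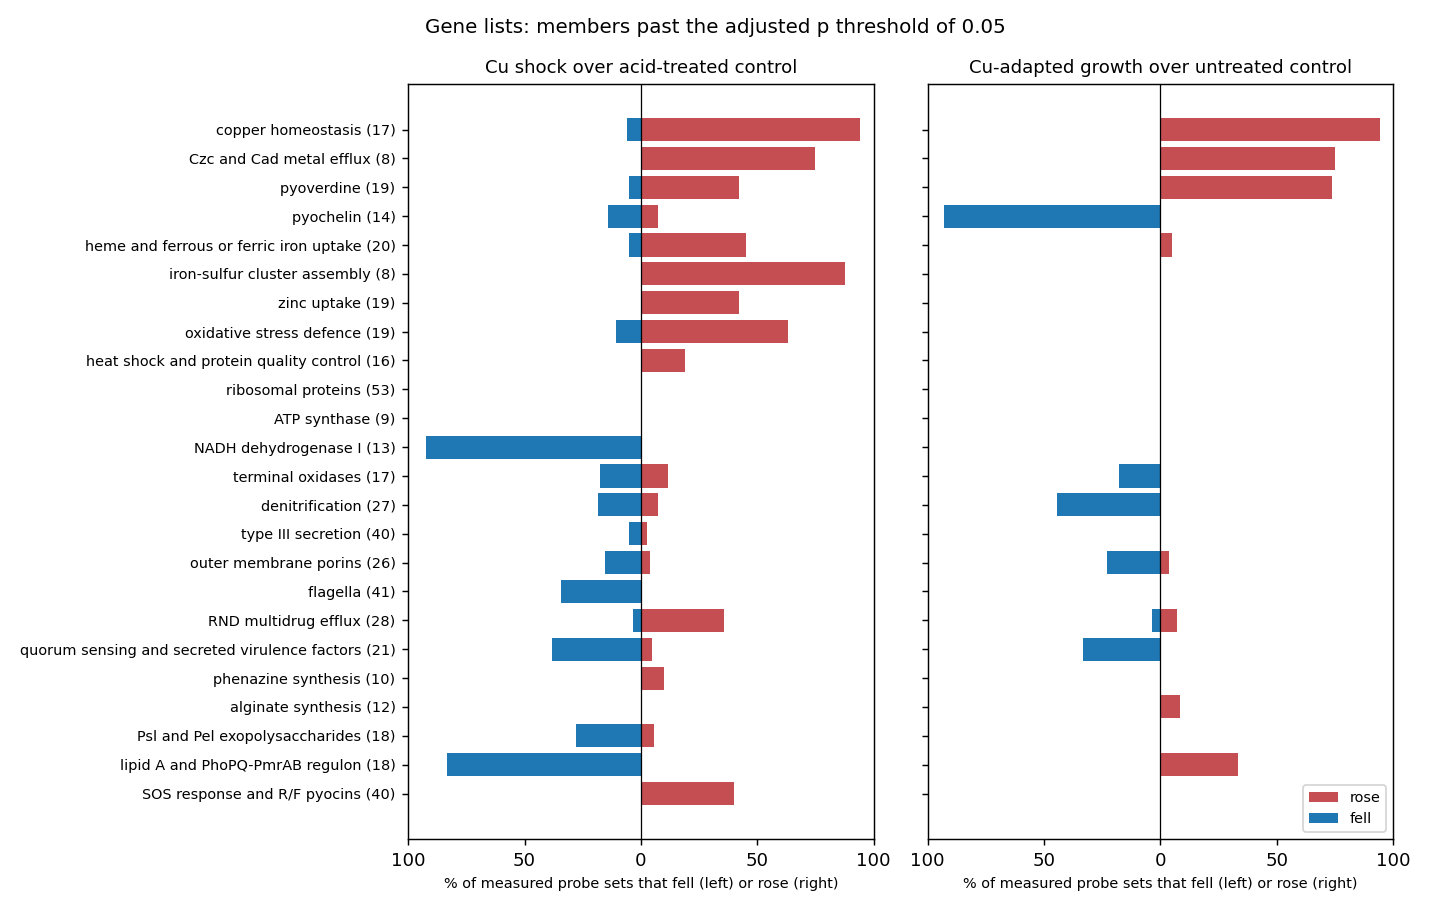
Percent of measured probe sets that rose (right) or fell (left) in each of the 24 gene lists, in Cu shock and in Cu-adapted growth. In the copper homeostasis list 16 of 17 rose in each comparison, while lipid A genes fell in Cu shock (15 of 18) and rose in Cu-adapted growth (6 of 18).

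The second comparison asked which transcripts differ after growth for about 6 h with copper. Its control was not acid-treated, so any effect of pH cannot be told apart from that of copper here. Of the 12 largest rises, 5 were those of copper homeostasis genes and 3 those of the Czc and Cad list (czcC, czcB and PA2523). PA2807 rose from 24.4 ± 7.98 to 58061 ± 8707 (SD, n = 2), the multicopper oxidase gene pcoA from 103 ± 5.26 to 53296 ± 4921 (n = 2), and czcC from 43 ± 5.88 to 16733 ± 1070 (n = 2). Transcripts for pyochelin synthesis and of the nir cluster, which holds the nitrite reductase gene nirS, made up 8 of the 12 largest falls. The transcript of nirC fell from 7483 ± 1327 to 174 ± 37.8 and that of pchA from 1606 ± 390 to 29.2 ± 12 (n = 2).

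In the limma fit, 338 of 5882 probe sets (5.7%) changed in Cu-adapted growth, 139 higher and 199 lower, against 967 at an unadjusted p below 0.05. At least 10-fold changes numbered 33 higher and 31 lower. The count depended on single arrays. It was 806 without shock control replicate 1 and 792 without shock control replicate 2, which are not part of this comparison but enter its spread. It was 133 without adapted replicate 1, 151 without adapted replicate 2, 163 without adapted control replicate 1 and 161 without adapted control replicate 2. Fitted to its own 4 arrays, the comparison gave 820, and with the replicate number as a block within each experiment 214.

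The 12 largest rises in Cu-adapted growth ranged from 5.97 to 10.49 log2 units and were led by PA2807 (10.49 ± 0.25, SE, adjusted p = 7.7e-07), pcoA (8.8 ± 0.48), ptrA (8.52 ± 0.34, from 254 ± 0.21 to 99423 ± 16240, n = 2) and PA3412 (8.31 ± 0.4, adjusted p = 5e-05). The porin gene opdT rose by 6.28 ± 0.45 and its neighbour PA2506 by 7.81 ± 0.47. PA4820, pcoB, czcC, czcB, PA2523 and PA3515 were also in this set, PA3515 (5.97 ± 0.84) not passing without adapted replicate 2 (adjusted p = 0.054). The 12 largest falls lay between -5.3 and -3.96, and 5 of them belonged to the nir cluster: nirC (-5.3 ± 0.25, adjusted p = 5e-05), nirL, nirM, PA0515 and nirS. The pyochelin genes pchA, pchD and pchE, arcD, hemN, PA3661 and the outer membrane protein gene oprG made up the rest. The transcript of arcD fell by 4.08 and that of hemN by 3.98, while PA3661 (-4.05 ± 0.66) did not pass without adapted control replicate 1 (adjusted p = 0.1) or adapted control replicate 2 (adjusted p = 0.064).

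Of 17 copper homeostasis genes, 16 rose and 0 fell in Cu-adapted growth (16 adjusted over the list alone), with a median of 4.3, camera adjusted p = 5.8e-25 and adjusted p = 0.066 with an estimated correlation. The genes PA3515, PA3516, PA3517, PA3518 and PA3519 rose by 5.97, 5.14, 4.16, 4.63 and 4.74, and the efflux genes PA3521, PA3522 and PA3523 by 4.3, 2.05 and 3.47. PA3920 rose by 2.98 ± 0.21 (SE), pcoB by 7 ± 0.39, copR by 2.83 ± 0.38, copS by 1.6 ± 0.25 and PA3520 by 1.5 ± 0.31. The call of copS was lost without any of the 4 arrays of this comparison (adjusted p = 0.055 to 0.091). PA3522 was not called without adapted replicate 1 (adjusted p = 0.11) or adapted control replicate 2 (adjusted p = 0.088). The call of PA3520 was lost without either adapted or either shock array or adapted control replicate 2 (adjusted p = 0.074 to 0.21). The transcript of cueR differed by -0.43 ± 0.2 (adjusted p = 0.37) and that of oprC by -1.86 ± 0.51 (adjusted p = 0.087), oprC passing without adapted control replicate 1 (adjusted p = 0.034) or either shock control (adjusted p = 0.021 and 0.023).

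Of 8 Czc and Cad metal efflux genes, 6 rose and 0 fell in Cu-adapted growth (6 adjusted over the list alone), with a median of 5.33, camera adjusted p = 1.6e-10 and adjusted p = 0.078 with an estimated correlation. The RND efflux genes czcC, czcB and czcA rose by 8.15 ± 0.61, 6.8 ± 0.35 and 5.86 ± 0.36 (SE), and PA2523 by 6.04 ± 0.39. None of 19 zinc uptake genes passed (0 adjusted over the list alone; median 0.57), with camera adjusted p = 0.0011 and adjusted p = 0.17 with an estimated correlation. Without either shock control, 5 zinc uptake genes rose.

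The siderophore lists went opposite ways in Cu-adapted growth. Of 19 pyoverdine genes, 14 rose and 0 fell (15 adjusted over the list alone), with a median of 2.25, camera adjusted p = 3.7e-15 and adjusted p = 0.16 with an estimated correlation. The peptide synthetase gene pvdL rose by 3.6 ± 0.43 (SE) and pvdA by 3.02 ± 0.28. The rises numbered 2 without adapted replicate 1, 8 without adapted replicate 2, 3 without adapted control replicate 1 and 5 without adapted control replicate 2. Of 14 pyochelin genes, 13 fell and 0 rose (13 adjusted over the list alone), with a median of -3.76, camera adjusted p = 1.3e-20 and adjusted p = 0.078 with an estimated correlation. The transcripts of pchA, pchD, pchE and PA4219 fell by 5.17, 4.38, 4.16 and 4.16, and 8 of the list fell without adapted control replicate 2. Of 20 heme and iron uptake genes, PA4358 rose (3 adjusted over the list alone; camera adjusted p = 0.054, adjusted p = 0.26 with an estimated correlation). This call was lost without either adapted array or either untreated control (adjusted p = 0.14 to 0.19), and 3 of this list rose and 1 fell without either shock control.

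Of 27 denitrification genes, 12 fell and 0 rose in Cu-adapted growth (20 adjusted over the list alone), with a median of -1.88, camera adjusted p = 2.1e-22 and adjusted p = 0.15 with an estimated correlation. The transcripts of nirL, nirM and nirS, the nitrite reductase gene, fell by 4.83, 4.62 and 4.5, and 19 of the list fell without either shock control. Of 17 terminal oxidase genes, ccoO2, ccoN2 and ccoP2 fell (-3.95 ± 0.27, -3.88 ± 0.28 and -3.39 ± 0.33, SE) and 0 rose (2 rose and 3 fell adjusted over the list alone). That list's median was 0.8 and its mean 0, with camera adjusted p = 0.78 and adjusted p = 0.8 with an estimated correlation, and 6 rose without either shock control. No member passed among 13 NADH dehydrogenase I genes (median -0.14, camera adjusted p = 0.21, adjusted p = 0.77 with an estimated correlation), 53 ribosomal protein genes (median -0.13, 0.064, and adjusted p = 0.78 with an estimated correlation) or 9 ATP synthase genes (median -0.43, 0.032, and adjusted p = 0.54 with an estimated correlation), with 0 adjusted over the list alone in each.

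Of 18 lipid A and PhoPQ-PmrAB genes, 6 rose and 0 fell in Cu-adapted growth (14 adjusted over the list alone), with a median of 0.85, camera adjusted p = 4.9e-08 and adjusted p = 0.23 with an estimated correlation. PA1559, the sensor gene pmrB, PA4775 and PA4774 rose by 1.59 ± 0.2, 1.54 ± 0.21, 1.51 ± 0.25 and 1.48 ± 0.21 (SE). The calls of PA1559 and pmrB were lost without adapted replicate 1 (adjusted p = 0.05 and 0.064), that of PA4775 without either adapted array or adapted control replicate 1 (0.053 to 0.12), and that of PA4774 without any of the 4 arrays (0.056 to 0.079). The rises numbered 13 and 12 without shock control replicates 1 and 2, 0 and 2 without adapted replicates 1 and 2, and 2 and 3 without adapted control replicates 1 and 2. Of 26 porin genes, opdT rose and 6 fell (1 and 7 adjusted over the list alone), with camera adjusted p = 0.015 and adjusted p = 0.16 with an estimated correlation. The transcript of PA2760 fell by 3.94, and that of oprD by 3.31. The falls numbered 3 without adapted replicate 2, and rises and falls numbered 4 and 9 without shock control replicate 1 and 3 and 9 without shock control replicate 2.

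Of 21 quorum sensing and secreted virulence genes, 7 fell and 0 rose in Cu-adapted growth (11 adjusted over the list alone), with camera adjusted p = 1.2e-07 and adjusted p = 0.17 with an estimated correlation. The quinolone signal gene pqsB fell by 2.85, hcnB by 2.24, phnA by 2.22 and hcnA by 2.02. Only hcnA among these passed whichever array was left out, and the others reached an adjusted p of 0.096, 0.065 and 0.072. The falls numbered 2 without adapted replicate 2, 3 without adapted control replicate 1 and 2 without adapted control replicate 2. Of 28 RND multidrug efflux genes, PA1436 and PA1435 rose by 4.52 ± 0.4 and 4.4 ± 0.32 (SE) and PA4374 fell (2 and 1 adjusted over the list alone), with camera adjusted p = 0.054 and adjusted p = 0.23 with an estimated correlation. The call of PA4374 was lost without either shock array or any of the 4 arrays of the comparison (adjusted p = 0.089 to 0.29), and rises and falls numbered 5 and 2 without either shock control. Of 12 alginate genes, algD rose by 2.65 ± 0.53 (1 adjusted over the list alone; camera adjusted p = 0.086, adjusted p = 0.23 with an estimated correlation). Its call was lost without either adapted or either shock array or adapted control replicate 2 (adjusted p = 0.058 to 0.17), and 2 rose without either shock control.

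Camera at the preset correlation called several lists in Cu-adapted growth in which no member passed, with 0 adjusted over the list alone in each. Fry gave an adjusted p of 0.031 for the SOS and pyocin list and 0.044 for the flagellar list. It did not call the heat shock list (fry adjusted p = 0.11) or the Psl and Pel list (0.15). The SOS and pyocin list had a median of -0.54 (camera adjusted p = 4.7e-13, adjusted p = 0.23 with an estimated correlation), and 17 and 15 of its 40 genes fell without shock control replicates 1 and 2. The flagellar list had a median of -0.33 (camera adjusted p = 1.8e-06, adjusted p = 0.23 with an estimated correlation), and 5 of 41 fell without either shock control. The heat shock list had a median of 0.54 (camera adjusted p = 0.0034, adjusted p = 0.4 with an estimated correlation), and 4 and 3 of 16 rose without shock control replicates 1 and 2. The Psl and Pel list had a median of -0.35 (camera adjusted p = 0.032, adjusted p = 0.38 with an estimated correlation), and 3 of 18 fell without either shock control. No member passed in the oxidative stress (median 0.13, camera adjusted p = 0.62, adjusted p = 0.71 with an estimated correlation), iron-sulfur (0.38, 0.11, adjusted p = 0.67 with an estimated correlation), type III secretion (-0.16, 0.11, adjusted p = 0.38 with an estimated correlation) or phenazine lists (0.35, 0.21, adjusted p = 0.4 with an estimated correlation). Without either shock control, 1 iron-sulfur gene rose and 1 oxidative stress gene fell.

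The camera calls numbered 13 lists in Cu shock (9 higher, 4 lower) and 14 in Cu-adapted growth (6 higher, 8 lower). The same test called 11 lists (4 higher, 7 lower) between the 2 controls, neither of which received copper. With an estimated correlation camera called 0 lists in these comparisons, in their difference and between the controls. The smallest camera adjusted p values were then 0.12, 0.066, 0.21 and 0.36. No list call held under that setting, not even that of copper homeostasis, with 16 of 17 genes higher in each copper comparison. A missing call under it therefore cannot show that a list did not shift. The fry test, which asks whether a list's genes move one way on balance, called 14, 15, 8 and 0 lists in the same 4 comparisons.

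The difference between the responses tested directly where a short shock and longer growth with copper diverged, each over its own control. The shock control was acid-treated, the adapted control was untreated, and the experiments were separate. In this test the time with copper therefore cannot be told apart from the acid matching or the experiment. The peroxide defence genes ohr and ahpF were higher in the shock response, and czcB, pcoA and 16 of 18 lipid A genes were lower in it. PA0874, PA3237, PA0201, PA3287 and ohr had the largest positive differences (7.36 ± 0.98, 7.27 ± 1.02, 6.39 ± 0.66, 5.7 ± 0.46 and 5.69 ± 0.28, SE). PA0201 was at 57900 ± 4047 in Cu shock and 494 ± 140 in Cu-adapted growth, with controls of 1964 ± 861 and 1498 ± 915 (n = 2). PA0747, PA2116, PA2411, PA4820 and PA0746 had the largest negative differences (-5.84 ± 1.21, -5.84 ± 0.64, -5.82 ± 0.73, -5.71 ± 0.66 and -5.52 ± 1.35). The calls of PA0747 and PA0746 were each lost without either shock array or any of the 4 adapted-experiment arrays (adjusted p = 0.067 to 0.085 and 0.082 to 0.12).

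The limma fit called 876 of 5882 differences (446 higher and 430 lower in the shock response), against 1831 at an unadjusted p below 0.05. The count was 255 and 228 without adapted replicates 1 and 2, 299 and 345 without adapted control replicates 1 and 2, 330 and 318 without shock replicates 1 and 2, and 1747 and 2017 without shock control replicates 1 and 2. With the replicate number as a block within each experiment it was 405. Median centring moved the median difference of all probe sets from -0.09 to 0.04, a shift that the list medians below exceed.

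Copper homeostasis genes split in this test. PA3523, PA3920, PA3522, PA3517, PA3521 and PA3518 were higher in the shock response by 4.98, 4.19, 3.85, 3.41, 2.6 and 2.58, while pcoA, pcoB, ptrA, PA2807 and cueR were lower (-4.32, -3.97, -2.82, -1.59 and -1.09). The list had 6 higher and 5 lower of 17 (6 and 5 adjusted over the list alone; median 0.72, camera adjusted p = 0.33, adjusted p = 0.72 with an estimated correlation), 4 and 2 without adapted replicate 1, and 4 and 3 without adapted replicate 2, adapted control replicate 2 or either shock array. PA3523, PA3920, PA3522, PA3517, pcoA and pcoB passed whichever array was left out, and ptrA passed except without adapted replicate 1 (adjusted p = 0.056). The calls of PA3518, PA3521 and cueR were each lost without either shock array or any of the 4 adapted-experiment arrays, with adjusted p between 0.054 and 0.16. That of PA2807 was lost without either adapted array, adapted control replicate 2 or either shock array (adjusted p = 0.079 to 0.13). Under median centring, quantile normalization or trimmed mean centring cueR did not pass (adjusted p = 0.077, 0.061 and 0.059), and with a pseudocount of 1 PA3518 and PA3521 did not pass (adjusted p = 0.055 and 0.091).

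Of 8 Czc and Cad genes, PA3690 was higher in the shock response by 5.53 ± 0.38 (SE) and 6 were lower, czcB by -5.09 ± 0.49 (1 and 6 adjusted over the list alone; median -4.12, camera adjusted p = 0.0055, adjusted p = 0.38 with an estimated correlation), and 2 were higher without shock control replicate 1. Of 18 lipid A genes, 16 were lower and 0 higher (17 adjusted over the list alone; median -2.63, camera adjusted p = 8.5e-14, adjusted p = 0.38 with an estimated correlation). PA4775 differed by -3.82 ± 0.35, pmrB by -3.25 ± 0.29 and pmrA by -3.1 ± 0.28. Of 14 pyochelin genes, 11 were higher and 0 lower (14 adjusted over the list alone; median 3.38, camera adjusted p = 7.5e-10, adjusted p = 0.31 with an estimated correlation), and 3 were higher without adapted control replicate 2, 5 without either shock array and 6 without either adapted array. Against the untreated controls, the pyochelin median was -1.49 and -1.8 on the Cu shock arrays and -0.7 and -1.17 on the acid-treated arrays. On the Cu-adapted arrays it was -3.68 and -3.47. Of 27 denitrification genes, 8 were higher and 0 lower (18 adjusted over the list alone; median 2.13, camera adjusted p = 1.5e-08, adjusted p = 0.38 with an estimated correlation), led by nirM (4.32 ± 0.4). That number was 4 without either shock array or adapted control replicate 1, 5 without adapted replicate 1 and 19 without shock control replicate 1, and 1 was lower without shock control replicate 2.

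Of 19 oxidative stress defence genes, 8 were higher in the shock response and oxyR lower (10 and 2 adjusted over the list alone; median 1.46, camera adjusted p = 8.3e-06, adjusted p = 0.21 with an estimated correlation). The genes ohr, ahpF, PA0848 and trxB2 differed by 5.69, 5.32, 5.08 and 4.3, and 5 of the list were higher without either adapted array or adapted control replicate 1. The call of oxyR was lost without either shock array or any of the 4 adapted-experiment arrays, and 2 were lower without either shock control. Of 40 SOS and pyocin genes, 22 were higher and 0 lower (37 adjusted over the list alone; median 1.27, camera adjusted p = 7e-16, adjusted p = 0.38 with an estimated correlation), with lexA at 2.78 ± 0.37 and recA at 2.65 ± 0.29 (SE). That number was 3 and 4 without adapted replicates 1 and 2, 3 and 7 without adapted control replicates 1 and 2, 4 and 3 without shock replicates 1 and 2, and 36 without shock control replicate 2. Of 8 iron-sulfur genes, 6 were higher and 0 lower (6 adjusted over the list alone; median 1.9, camera adjusted p = 7e-05, adjusted p = 0.55 with an estimated correlation), iscR by 2.97 ± 0.45. It was 1 without adapted replicate 2 and 2 without adapted replicate 1, either untreated control or either shock array.

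**Figure D3:**
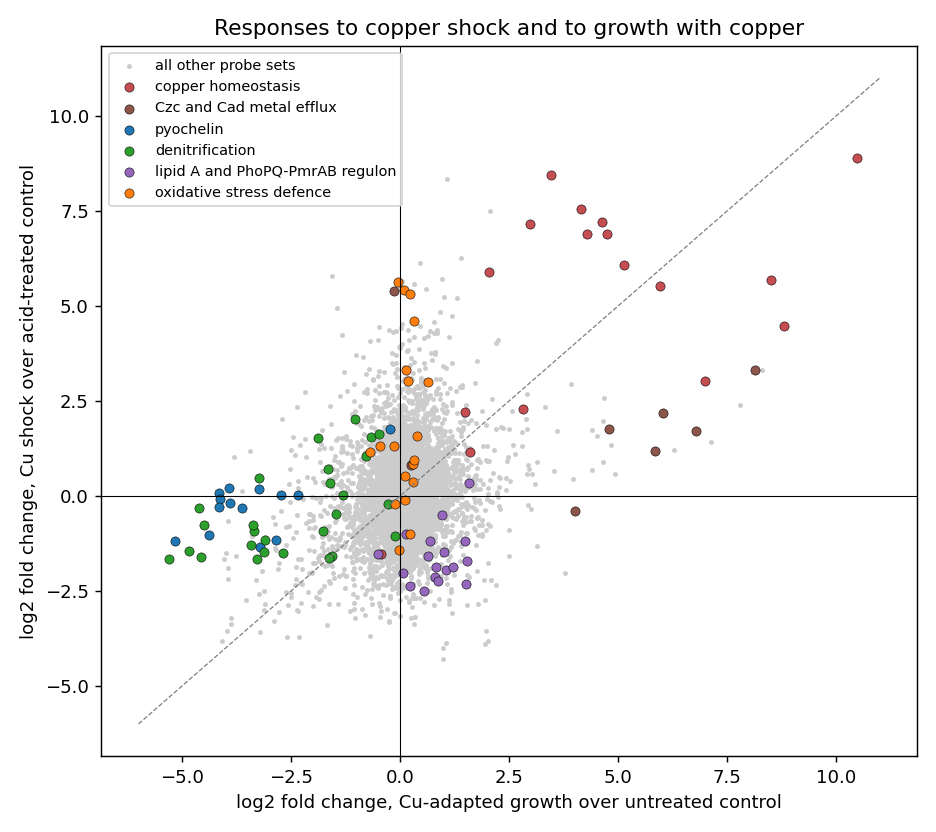
Log2 fold change in Cu-adapted growth (x axis) against Cu shock (y axis) for 5882 probe sets, with members of 6 gene lists coloured and the line of equal response dashed. Lipid A genes lie below the line, with a median difference of -2.63, and pyochelin genes above it, with a median difference of 3.38.

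Genes changed the same way in both comparisons numbered 166 when added over the 64 that rose and the 102 that fell in both. Independent lists would share 20.4 and 31.1, and Fisher's exact tests gave p = 3.11e-19 and 6.36e-33 (Benjamini-Hochberg adjusted over 4 tests, 6.22e-19 and 2.54e-32). Opposite changes numbered 14 for shock up with adapted down, against 29.2 (Fisher's exact p = 0.00105, adjusted 0.0014), and 15 for the reverse, against 21.7 (p = 0.124, adjusted 0.124). The 4 tests take probe sets as independent, whereas changed genes lay in runs along the gene order. Both comparisons also share the estimate of spread. These p-values therefore need not hold and do not measure the spread between cultures. Across all probe sets, which are not independent, the fold changes correlated at a Pearson r of 0.262 and a Spearman rho of 0.175. The shared number was 84 and 93 without adapted replicates 1 and 2, 94 and 97 without adapted control replicates 1 and 2, 100 without shock replicate 2, and 346 and 330 without shock control replicates 1 and 2. The genes named for both comparisons by the rule of largest change were PA2807 among the rises and arcD and hemN among the falls.

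The last comparison set the acid-treated against the untreated control, which also came from a separate experiment. The flavohemoglobin gene fhp, for nitric oxide detoxification, was higher by 4.51 ± 0.51 (SE, adjusted p = 0.018), from 177 ± 126 to 3994 ± 1369 (n = 2), and ppyR by 4.05 ± 0.45. PA3240, PA1210 and PA3919 were higher by 3.02, 2.95 and 2.9, and PA0493, PA3530, PA0495, PA0494 and PA4675 lower (-2.6, -2.48, -2.27, -2.01 and -2). Of 27 denitrification genes, 7 were higher and 0 lower (19 adjusted over the list alone; median 1.91, camera adjusted p = 7.2e-16, adjusted p = 0.36 with an estimated correlation). Neither control received copper. The fit called 72 probe sets (51 higher, 21 lower), against 1029 at an unadjusted p below 0.05.

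The count of these calls fell without any single array of the adapted experiment or of Cu shock, and rose without either acid-treated control. The count was 0 without adapted replicate 1, 0 without adapted replicate 2, 5 without adapted control replicate 1, 0 without adapted control replicate 2, 1 without either shock array, 215 without shock control replicate 1 and 1812 without shock control replicate 2. The denitrification calls numbered 0 without either adapted or either shock array or adapted control replicate 2, 1 without adapted control replicate 1 and 20 without shock control replicate 2. The 10 genes named for the controls each lost their call under at least 4 of the 8 omissions. Median centring moved the share of higher calls from 70.8% to 56.4% and the median of all probe sets from 0.05 to -0.07.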

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

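Everything in this part was set apart because the shock response and the adapted response differed in a direct test. Groups of 2 arrays were too small for the test for a sample far from the others. The tests of the lipid A pattern below were all chosen after the result was seen.

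The responses differed for 876 probe sets, a count that ran from 228 to 2017 when single arrays were left out. Higher in the shock response were PA0874 (7.36), PA3237 (7.27), PA0201 (6.39), PA3287 (5.7) and ohr (5.69), in log2 units. Lower were PA0747 (-5.84), PA2116 (-5.84), PA2411 (-5.82), PA4820 (-5.71) and PA0746 (-5.52), and the acid-treated controls were far apart for PA0747 (10809 and 1133), PA0746 (22347 and 1883) and PA2116 (7042 and 2496).

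The list medians that differed were those of Czc and Cad metal efflux (-4.12), pyochelin (3.38), denitrification (2.13), iron-sulfur cluster assembly (1.9), oxidative stress defence (1.46) and the SOS response with pyocins (1.27). A further 3 were pyoverdine at -1.13 (1 higher and 4 lower of 19; 1 and 7 adjusted over the list alone; camera adjusted p = 0.0076, adjusted p = 0.63 with an estimated correlation), heme and iron uptake at 0.33 (4 higher of 20; 4 adjusted over the list alone; camera adjusted p = 0.038, adjusted p = 0.38 with an estimated correlation) and NADH dehydrogenase I at -1.23 (3 lower of 13; 9 adjusted over the list alone; camera adjusted p = 4.9e-05, adjusted p = 0.63 with an estimated correlation). The 4 lower pyoverdine calls numbered 0 or 1 without either adapted array, either untreated control or either shock array, and 7 without either acid-treated control. The 3 NADH dehydrogenase I calls numbered 0 without either adapted array, either untreated control or shock replicate 2, 12 without shock control replicate 1 and 7 without shock control replicate 2. Of the heme and iron uptake list, 6 were higher and 2 lower without shock control replicate 1. The higher pyoverdine call, that of pvdS, was lost without any single array other than an acid-treated control. With an estimated correlation none of these list differences passed.

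In the lipid A and PhoPQ-PmrAB list, 15 of 18 genes fell in Cu shock and 6 rose in Cu-adapted growth, with a median difference of -2.63. The 6 rises numbered 0 without adapted replicate 1, 2 without adapted replicate 2 or adapted control replicate 1 and 3 without adapted control replicate 2, and with an estimated correlation the list's adjusted p was 0.35, 0.23 and 0.38 for shock, adapted growth and their difference. Relative to the untreated controls, the list's median lay at 0.24 and 0.61 on the acid-treated arrays and at -1.06 and -1.19 on the Cu shock arrays. If the experiments were comparable, a rise in the acid-treated controls alone would have left the Cu shock arrays near the untreated level. The untreated controls came from a separate experiment, so these values cannot settle how much of the falls came from such a rise. Array scaling does not account for the difference, since the median stayed between -2.63 and -2.5 under 5 scalings. The separate experiments, the lack of an acid-treated control for Cu-adapted growth, and a response of these genes that depends on the time with copper, remain open and untested.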

How the results depend on the processing

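Every comparison below is with the counts in the report, and Cu shock against the untreated and against all 4 controls was chosen after the data were seen. Under other scalings, pseudocounts, filters, the robust prior and the 2-fold minimum, the counts stayed within 1.5-fold (Cu shock 1494 to 1844, Cu-adapted growth 319 to 358). Without an intensity trend the controls gave 19, and the cause was not tested.

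With the replicate number as a block within each experiment, Cu-adapted growth gave 214, the difference 405 and the genes changed the same way 108, while Cu shock gave 1428, and 25 of 79 named difference calls were lost. With the replicate block over all arrays the controls gave 26. Deviations of arrays with the same number correlated at -0.056 in the shock experiment and 0.005 in the adapted experiment, so no shared deviation was seen. The labels do not say whether the numbers pair the cultures, and a paired fit loses degrees of freedom.

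Fitted to its own 4 arrays, Cu shock gave 781, with 27 of 106 named calls lost, and Cu-adapted growth 820, with 0 of 59 lost. The first fit has fewer arrays and a noisy pair, and the second leaves that pair out. This fit cannot give the difference or the controls, and the block within experiments cannot give the controls. With an estimated correlation 0, 0 and 0 lists were shifted in Cu shock, Cu-adapted growth and their difference, and fry gave 14, 15 and 8.

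Leaving out single arrays gave 879 to 2467 genes in Cu shock, 133 to 806 in Cu-adapted growth, 228 to 2017 for the difference, 0 to 1812 for the controls and 84 to 346 changed the same way. List counts were 13 to 14, 13 to 16 and 9 to 11. The higher ends came without an acid-treated control, which takes the widest pair out of the spread. The difference of PA3515, not called at -0.44, ran from -1.86 to 0.98, and was 0.976 without adapted control replicate 1, 0.038 without adapted replicate 2 and 0.177 without shock control replicate 2. The cause was not tested.

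Against the untreated controls Cu shock changed 2060 genes, and against all 4 controls 2271. PA2393, nirC and PA0513 reversed against the untreated controls, to -0.187, 0.381 and 0.255, because their acid-treated and untreated signals differed. Of the values of called named genes under settings other than single omissions, 1501 of 1582 kept their call in Cu shock, 748 of 762 in Cu-adapted growth, 883 of 943 in the difference and 96 of 110 in the controls. Under single omissions these were 749 of 848, 417 of 472, 429 of 632 and 25 of 80. Low signals limit the precision, since no background value stood beside them.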

Other observations

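All tests in this part were chosen after the results were seen. Changed genes lay in runs along the gene order. Runs of at least 5 neighbouring genes changed the same way numbered 52 in Cu shock (328 genes), against a mean of 0.82 and at most 6 in 1000 shuffles. In Cu-adapted growth they numbered 10 (81 genes), against at most 1. The shuffles treated neighbouring genes as independent, so they show that calls cluster along the gene order but not why. In Cu shock, 13 genes of the O-antigen region from PA3145 to PA3157 had a median of -2.19, and 7 genes from PA2282 to PA2288 a median of 3.51. In Cu-adapted growth, 20 genes from PA0075 to PA0094, which include the type VI secretion genes hcp1, icmF1 and clpV1, had a median of -1.74. This region also held runs that fell in Cu shock, from PA0073 to PA0079, PA0082 to PA0089 and PA0093 to PA0097, with medians of -1.32, -1.64 and -1.34.

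The genes arcD, hemN, ccoN2, dnr, PA4348, PA2119, PA3913 and PA1673, picked after the results were seen as falling in both comparisons and linked to oxygen limitation, do not stand for all such genes: the denitrification list lay above the untreated controls on both Cu shock arrays, at 1 and 1.05. Relative to the untreated controls, the medians of these 8 genes were 0.69 and 1.45 on the acid-treated arrays and -2.13 and -2.38 on the Cu shock arrays. These values cannot settle how much of the fall in shock came from a rise in the acid-treated controls. Picking genes that fell in both comparisons favours low Cu shock signals and high untreated signals, and the arrays came from separate experiments. Lower activity of the regulator ANR was tested on 15 other genes it may act on, and 11 of 15 were below their controls in both comparisons (73.3%, against 24.1% of all genes). The test left this open, since PA1746 rose in Cu shock (0.72, adjusted p = 0.045) and fell in Cu-adapted growth (-2.53), and arcA, arcB and arcC fell in Cu-adapted growth (-2.33, -1.98 and -2.42) but did not pass in Cu shock (0.22, 0.47 and 1.07). Several of the 15 had been visible before the test. Some also lie in the gene order near genes picked for falling in both comparisons: PA0526 near dnr, PA3911 and PA3912 near PA3913, and arcA, arcB and arcC near arcD. The 15 are therefore not separate from the picked genes. Counted among the 11, azu differed by -0.39 and -0.02 and passed in neither comparison.

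The 2 acid-treated controls lay far apart, with an SD of their log2 differences of 1. Copper-treated RNA in 1 of them does not account for the gap, since the copper homeostasis genes differed by a median of 0.25, and neither do different intensity distributions, since the SD was 0.98 after quantile normalization, against 0.56 for the widest other pair. For a culture in a slower-growing state, which was left open, ribosomal protein genes were at a median of -1.42 in shock control replicate 1 relative to replicate 2, below all of 10000 random lists of like brightness, 95% of which lay at -0.88 to -0.27 and the lowest at -1.16. This gap had been visible before the test, and those lists take genes as independent, whereas the estimated correlation within the ribosomal list was 0.94.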
